A study of Mus musculus with 388 samples.

How the data were processed

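Each of the 388 samples is 1 cell, and the cells' values stand together in 1 table of 25000 genes by symbol. Per the file headers and values, the deposited values are expected counts, estimates that need not be whole: 82279 values, 4.91% of those above 0, were not whole numbers. The submitters' processing notes name HISAT, HTSeq 0.6.0, StringTie 1.3.3b and the build GRCm38; how the authors used each of them, and their gene annotation, are not given in the sources used here. Per the labels' protocols, cells were lysed in a detergent buffer, and their RNA was reverse transcribed and amplified as a whole before library preparation, with no mention of molecular identifiers. Reads are therefore counted after amplification, and a few molecules of a rare transcript can give many counts in 1 cell. No strand information is given for the counting, so reads of overlapping antisense genes cannot be told apart, and closely related genes such as histone and Ly6 family members may share reads.

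Expected counts were rounded to whole numbers; 8857 genes were then at 0 in all cells. Every table column was matched by its name to 1 group and title set, and none to the title of a single cell; 0 columns were left unused, and 0 columns were duplicates. Per the labels, tamoxifen was given at embryonic days 12.5 and 14.5. Groups were taken from the labels, 187 Tomato+ and 201 Tomato− cells. Cell titles give 2 orders and 8 sets (5 Tomato+ and 3 Tomato−). The table's column names give 12 library codes in order 1, of which 7 hold cells of both groups (143 cells). What the order and set numbers stand for is not given in the sources used here. Cells with at least 1000 genes and 10000 counts were kept, 386 in all; the 2 left out held 7927 and 4014 counts. The kept cells summed to 142533338 counts in Tomato+ and 125804595 in Tomato−, and the shallowest kept cell held 18031. Median mitochondrial shares were 1.24% in Tomato+ and 0.860% in Tomato− cells, 1.41% and 2.14% in order 1 and 0.689% and 0.736% in order 2. The share of cells with a count of 1 gene planned for comparison is not reported here. No doublet caller was run; wells with more than 1 cell were looked for through Lepr reads in blood-type cells.

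Counts were summed over the cells of a group within each title order and scaled to CPM of the sum. The value of a gene is log2 of the ratio of CPM + 1, Tomato+ over Tomato−, within each order, averaged over the 2 orders; a ratio on this scale understates changes of low genes. No test was made, since cells are not replicates. Sums are given with exact Poisson and shares of cells with exact Clopper-Pearson 95% intervals, and a count of 0 allows up to 3 counts. Gene lists, named-gene rule, cell type markers, designs and most alternatives were fixed before the data were examined. Named genes had at least 20 CPM and a count in at least 20% of cells in the higher group, a log2 ratio of the same sign and more than 1.5-fold in both orders, and the same sign for the mean of per-cell CPM. They were ranked by the smaller of the order ratios, and the first 12 in each direction were taken, without mitochondrial, ribosomal protein and predicted genes. Kit, Kitl, Pdgfra, Lepr, Ptprc and Pecam1 were added, with up to 2 examples per list, and the first 6 in each direction within the Lepr+ stroma-like class. A list member counts as higher or lower when it passes the size part of this rule.

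The 29 gene lists covered Lepr+ bone marrow stroma, haematopoietic niche factors, adipogenic, osteogenic and chondrogenic lineages, Sca1+ fibroblast-like stroma, tendon, pericytes, endothelium, myeloid, lymphoid, erythroid, megakaryocyte, mast, Schwann and muscle cells, cell cycle, stress, receptor tyrosine kinase feedback, Wnt, BMP and TGF-beta, Hedgehog, Notch, insulin-like growth factor, skeletal stem cell markers, collagens, matrix remodelling, interferon and inflammation. All mitochondrially encoded and ribosomal protein genes were added as technical lists. A member was measured when it had a count in the summed cells, and 2 list genes were absent from the table by symbol. Each list's median was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these cells. Coordinates come from GENCODE M21 on GRCm38, in which 24685 symbols matched.

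For cell classes, counts were log-normalised, 2000 variable genes and 20 components were taken, and 15 nearest neighbours were clustered by the Leiden method at resolution 0.8. A cluster took the name of a class when at least 3 of the class's fixed markers stood among its 10 leading genes and at least 3 were detected, which means 5 counts in 25% of its cells. A cluster led by markers of no class was called Lepr+ stroma-like from its detected markers, 21 or 22 of 22 in each of the 7 such clusters. This was a default name: 0 of the 22 stood among the leading genes of any cluster, and the myeloid-like cluster also detected 18 of 22. A second rule for single cells asked for 3 markers of a type at 100 CPM and 10 counts or more, after counts under 1% of the highest count of the same library pool were set to 0. To compare shares across depths, cells were thinned to 150000 counts, which left out 4 Tomato+ and 13 Tomato− cells. For sets, 24 cells were drawn 20 times.

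The procedure was tested on simulated data in which 200 of 25000 genes were changed between the groups. The changed genes were drawn only from those at 20 CPM or more in both orders, so the rates below do not cover lower genes. Of genes changed 2-fold 77.6% passed the size rule, of those changed 4-fold 95.5%, and of those changed 8-fold 98.5%, with median log2 ratios of 1.09, 1.98 and 3.01. Of 6623 unchanged genes at the CPM minimum, 313 (4.73%) passed, so passing the rule alone does not set a gene apart from the spread between cells. A further 20 draws changed no gene; the simulation takes cells as independent and holds no differences between title sets. An upper bound on the simulated spread was removed, and the draws were repeated, after a first result was seen. Alternatives covered pseudocounts of 5 and 0.1 CPM, TMM factors from edgeR 4.0.16 and size factors from DESeq2 1.42.0 (for scaling only), per-cell means, sums over both orders, other cell filters, thinning, removal of the 10 deepest cells, removal of Ptprc- or Pecam1-bearing cells, other clustering settings, and leaving out each title set. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3, were used.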

Results

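Single-cell RNA sequencing was carried out on bone marrow stromal cells of 2-month-old C57BL/6 mice that carry a tamoxifen-inducible Cre at the Kit locus and a Cre-activated tdTomato reporter. Tamoxifen was given before birth, so that red fluorescence marks adult cells whose fetal precursors expressed Kit, the receptor for stem cell factor. Cells were sorted as PDGFRα-positive and negative for CD45, Ter119 and CD31, which mark blood, erythroid and endothelial cells. The cells fall into 8 title sets that belong to 2 title orders. Tomato+ cells made up the sets P1, P2 and P3 of order 1 (94, 5 and 40 cells) and P1 and P2 of order 2 (24 cells each), and Tomato− cells the set N2 of order 1 (60 cells) and N1 and N2 of order 2 (71 and 70 cells). The total count per cell had a median of 678586 and ran from 4014 to 3833473, with medians of 725276 in Tomato+ and 637863 in Tomato− cells. A median of 4416 genes had a count. After removal of 2 shallow Tomato+ cells of the set P3, 386 cells remained. No animal is named in the labels, so each group is 1 sample: the differences have no replicate check, no test was made, and the intervals cover counting error only. Reads without molecular identifiers are not independent molecules. The sets also differ in sex-linked reads: with at least 5 counts required, 20 of the 38 cells of the Tomato+ set P3 of order 1 carried Xist reads alone, whereas 59 of the 94 cells of the set P1 of order 1 carried Y-linked reads alone.

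The first comparison asked whether adult cells descended from Kit-expressing fetal precursors still carry Kit transcripts, and whether the sorting gate held. Kit (chromosome 5, 75574916 to 75656722 of GRCm38) was higher in Tomato+ cells in both title orders. In order 1 its summed counts came to 16.9 CPM in Tomato+ (16.1 to 17.6) against 0.33 CPM in Tomato− cells (0.17 to 0.60). In order 2 the levels were 47.6 CPM (45.2 to 50.1) and 8.94 CPM (8.35 to 9.57). The log2 ratios were 3.74 and 2.29, with a mean of 3.02; the value was 1.68 when all cells of a group were summed over both orders. Kit was a rare transcript in both groups: 37 Tomato+ cells had a count (20% of the group, 14.5 to 26.5) against 23 Tomato− cells (11.4%, 7.39 to 16.7). The shares were 9.19% and 3.98% when 5 counts were required, and 11.4% and 6.47% after counts under 1% of the pool maximum were set to 0. After each cell was thinned to 150000 counts, they were 13.8% (9.14 to 19.7) and 9.04% (5.36 to 14.1), which overlap. The unthinned shares were 13.9% and 13.3% in order 1, and 37.5% (24 to 52.6) and 10.6% (6.08 to 16.9) in order 2, where thinned cells gave 22.9% (12 to 37.3) and 8.15% (4.14 to 14.1). Without the set P1 of order 1 the mean ratio was 2.43. Within the Tomato+ sets of order 1 the Kit level was 20.1 CPM in P1 and 7.5 CPM in P3.

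The leptin receptor Lepr, which marks perivascular marrow stroma, had a count in all 386 cells, and so did Kitl, the gene of the Kit ligand. A count need not mean expression, since reads can be shared within a library pool. With counts under 1% of the pool maximum set to 0, Lepr was met in 89.2% of Tomato+ and 84.1% of Tomato− cells, and Pdgfra in 66.5% and 69.2%. In Tomato− cells of order 1 these shares were 65% and 38.3%. Lepr lay at 3657 and 4261 CPM in Tomato+ and Tomato− cells of order 1 and at 4141 and 4381 CPM in order 2, a mean log2 ratio of −0.15. Kitl lay at 1693 and 2020 CPM in order 1 and at 1630 and 1511 CPM in order 2, a mean of −0.07. Pdgfra, the gene of the sorting antigen, had a count in 96.8% of Tomato+ (93.1 to 98.8) and 97% of Tomato− cells (93.6 to 98.9), and its log2 ratio was −0.90 in order 1 and 0.16 in order 2. Ptprc, which encodes CD45, had a count in 2 Tomato+ cells (1.08%, 0.131 to 3.85) and in 32 Tomato− cells (15.9%, 11.2 to 21.7). All of these lay in order 2; in order 1, where 0 cells of either group had a count, shares of up to 2.19% in Tomato+ and 5% in Tomato− cells remain possible. Pecam1, which encodes CD31, had a count in 30 Tomato+ (16.2%, 11.2 to 22.3) and 23 Tomato− cells (11.4%, 7.39 to 16.7); with 5 counts required, the shares were 7.03% and 7.46%.

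The second comparison asked which genes differ most between the stromal descendants of Kit-expressing precursors and the remaining stroma. Besides Kit, the genes higher in Tomato+ cells in both orders were Cd300lg, Pak3, Rfxank, Mageh1, Nek9, Map2k5, Cavin2, Emcn, Tspan7, Tshz3 and Dph1. Cd300lg, a CD300-family receptor of endothelial cells, had log2 ratios of 2.48 and 2.29 (30.6 against 4.65 CPM in order 1, 61 against 11.7 CPM in order 2). A single cell held 60.4% of its Tomato+ counts in order 1 and 39.9% in order 2. Fewer Tomato+ cells (10.3%) than Tomato− cells (14.4%) had 5 or more Cd300lg counts. The p21-activated kinase gene Pak3 gave 2.14 and 1.96, and Rfxank, a subunit of the RFX complex at MHC class II promoters, gave 3.94 and 1.83. Map2k5, the kinase upstream of ERK5, gave 1.93 and 1.54, the kinase gene Nek9 2.18 and 1.57, and the zinc-finger gene Tshz3 3.47 and 1.36. Mean ratios were 1.68 for Mageh1 and 2.02 for Dph1, a gene of diphthamide synthesis. The caveolar coat gene Cavin2 had a mean of 1.68, the endothelial sialomucin gene Emcn 1.71 and the tetraspanin gene Tspan7 1.70. These 3 and Cd300lg moved when cells holding 5 or more counts of Ptprc or Pecam1 were left out together. Emcn was then at −1.10, Tspan7 at −0.64, Cavin2 at 0.20 and Cd300lg at 1.16, while Kit was at 3.68. Pecam1 reached 5 counts in 13 Tomato+ and 15 Tomato− cells, and Ptprc in 0 and 12. In Emcn, 1 cell held 95.5% of the Tomato+ counts of order 2 and 1 cell 98.2% of the Tomato− counts of order 1, and Emcn was at 0.17 without the set P2 of order 2. Ratios were also taken within batches with cells of both groups, which are the shared library codes of order 1 and, in order 2, the sets numbered 1 and those numbered 2. The shared codes were summed as 1 batch. Pairing the sets of order 2 by number is an assumption, since the labels do not say what the numbers stand for. Emcn was then at −0.33, −1.99 and 4.43 (mean 0.70) and Tspan7 at −1.51, 1.05 and 2.35 (mean 0.63), so that their direction differed between batches. Cavin2 had a mean of 0.98 and Dph1 was at 0.01 in the sets numbered 1, while Kit was at 4.11, 2.16 and 2.32. Without the set P3 of order 1, Tspan7 was at 0.16 and Cd300lg at 1.58, and without the set P1 of order 1, Rfxank was at 1.2, Nek9 at 1.12 and Dph1 at 0.93. Map2k5 was at 1.10 without the 5 cells of the set P2 of order 1, and Cavin2 at 1.07 without the set P2 of order 2. A single cell held 60.7% of the Tomato+ Map2k5 counts of order 1.

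Among the genes lower in Tomato+ cells, the leukocyte tetraspanin gene Cd53 had log2 ratios of −4.58 and −5.20, with 0.19 against 42.8 CPM in order 2. Serpinb1a, an inhibitor of neutrophil proteases, had 0.68 against 136.1 CPM in order 2; in order 1 its single Tomato+ count stood against counts that all came from 1 Tomato− cell. Lsp1, a leukocyte cytoskeletal gene, had a mean ratio of −3.82 and Cyfip2, of the WAVE actin complex, −3.28. Rrm2, a subunit of ribonucleotide reductase, had ratios of −4.10 and −3.40, the histone gene Hist1h2ap a mean of −3.63, the centriole gene Cenpj −4.01 and the centromere gene Cenpl −2.25. The remaining lower genes were Fam49b at −3.80, the glycogenin gene Gyg at −2.43, Tent4a at −2.46 and Hps5 at −2.10; Tent4a was at −4.01 without the set P1 of order 1 and Hps5 at −3.41 without P1 of order 2. Single cells carried much of the Tomato− signal of order 1: 99.4% of the counts of Cd53, 99.2% of Fam49b, 97.1% of Cyfip2, 93.8% of Tent4a and 90.2% of Rrm2 lay in 1 cell each. Without the cell with the most reads in each group and order, the ratios of order 1 were −0.12 for Cd53, 0.00 for Serpinb1a, −0.27 for Gyg, −0.32 for Cyfip2, −0.92 for Lsp1 and −1.49 for Rrm2, and those of Fam49b and Tent4a turned to 1.37 and 0.59, which left Tent4a at a mean of −1.07; Cenpj was at −3.93. Without cells holding 5 or more counts of Ptprc or Pecam1, the mean ratios were −0.21 for Hist1h2ap, −0.78 for Cyfip2, −2.03 for Rrm2, −2.46 for Cd53 and −2.51 for Serpinb1a. Without the set N2 of order 2 they were −2.80 for Cd53, −2.19 for Cyfip2, −2.74 for Hist1h2ap, −3.00 for Fam49b, −4.35 for Serpinb1a and −1.55 for Gyg.

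**Figure D1:**
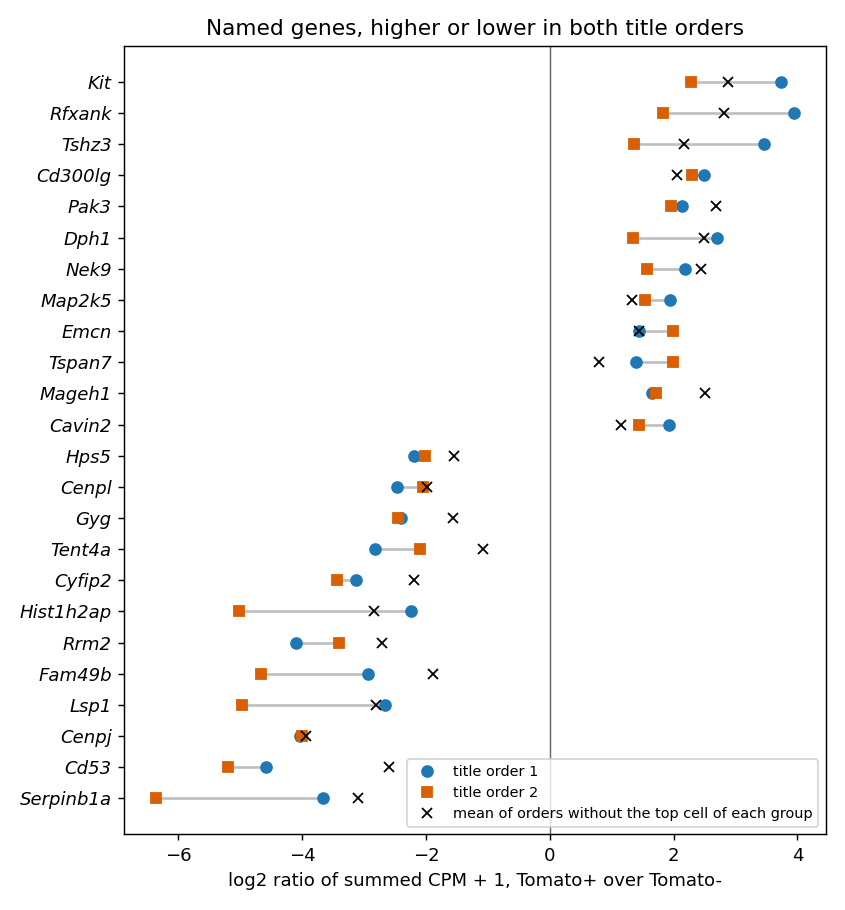
Log2 ratio of summed CPM plus 1, Tomato+ over Tomato−, for the 12 genes named in each direction; circles and squares are title orders 1 and 2, and crosses are the mean of the orders without the cell with the most reads in each group and order. Kit lies at 3.74 and 2.29 and Serpinb1a at −3.67 and −6.35.

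Differences between the groups were largely particular to each order. Across 6994 genes at 20 CPM or more, the log2 ratios of the orders correlated with r = 0.126 (Spearman rho = 0.108) and had the same sign in 54.3%; this is a relation across genes, which are not independent replicates. In 20 simulations of these cells with no gene changed, the top-ranked gene reached a smaller order ratio of 1.48 to 2.55 upward and of 1.58 to 2.30 downward in size, and the gene at rank 12 one of 1.05 to 1.29 and of 1.13 to 1.38. The smaller order ratios of the 12 higher genes, from 1.34 for Dph1 to 2.29 for Kit and Cd300lg, thus did not pass the highest values that the top-ranked unchanged genes reached, and those of Dph1, Tshz3, Tspan7, Emcn and Cavin2 lay below their lowest, while Cd53, Cenpj, Serpinb1a, Rrm2, Cyfip2, Fam49b, Lsp1 and Gyg, at −2.41 or further, lay beyond it. At rank 12, both Dph1 at 1.34 and Hps5 at −2.01 lay beyond the simulated range of that rank. The simulation holds no differences between title sets, and the order 1 ratios of most of the lower genes rested on 1 cell.

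Of 22 measured members of the Lepr+ bone marrow stroma list, only the chemokine gene Cxcl14 passed the size rule, at 1857 against 823.5 CPM in order 1 and 4312 against 2716 CPM in order 2 (log2 ratios 1.17 and 0.67). Cxcl12, Gas6, Csf1, Grem1 and Nt5e, chosen after their values were seen, lay at 0.91, 1.17, 1.3, 0.95 and 1.90 in order 1 and at 0.14, 0.22, −0.16, 0.10 and 0.47 in order 2. The list median was 0.17, at percentile 94.4 of 10000 random lists matched on expression. Cxcl14 was at 0.23 without the set P1 of order 1 and at 0.11 with all cells summed over both orders. Among 18 haematopoietic niche factors (median 0.10, percentile 73.1), the cytokine gene Il15 was higher at 0.91 and the pleiotrophin gene Ptn lower at −1.28. Ptn nevertheless had a count in a larger share of Tomato+ (34.1%) than of Tomato− cells (23.4%). Without the set P1 of order 1, Il15 was at 0.54 and Ptn at −0.71, and Ptn was at −2.06 without P1 of order 2 and at −0.07 with all cells summed. The adipogenic lineage list had a median of 0.45 (0.39 and 0.20 in the orders, percentile 99.8), with 1 of 24 members higher, the preadipocyte factor gene Zfp423 at 1.40. Its median was 0.18 without cells holding Ptprc or Pecam1 counts. The osteogenic list had a median of 0.41 (percentile 99.9), from 0.86 in order 1 and 0.00 in order 2, and 0 of 27 members passed; the set N2 is the only Tomato− set of order 1, so that values without it are those of order 2. Col1a1, the main bone collagen gene, was at 1.62 and −0.17. Of 16 chondrogenic genes 0 passed (median 0.00, percentile 56.6). Of 20 skeletal stem cell markers, Fgfr3 at 1.02 and the endoglin gene Eng at 0.99 were higher (list median 0.14, percentile 82.4); Fgfr3 was at 0.58 without the set P1 of order 1 and at 0.03 with all cells summed, and Eng at 0.61 without cells holding Ptprc or Pecam1 counts.

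The fibroblast and mural lists had medians below 0, with few members past the size rule. The Sca1+ fibroblast-like list had a median of −0.85 (−0.49 and −1.17 in the orders, percentile 0.00), with 2 of 24 members lower: Ly6a, which encodes Sca1, at −2.19 and the gelsolin gene Gsn at −1.36. Scara5, a ferritin receptor gene, lay at 1.75 and Dpt at 1.57, both from order 1; these and Kcnj8 were chosen after their values were seen. Ly6a was at −0.30 without the set N1 of order 2, and Gsn at −0.60 and Ly6a at −1.27 without P1 of order 1. The pericyte and smooth muscle list had a median of −1.26 (−1.77 and −0.87, percentile 0.00), with 2 of 13 members lower. These were the pericyte marker Rgs5 at −3.23 and the potassium channel subunit gene Abcc9 at −1.53. In order 1, 1 cell held 93.4% of the Tomato− Rgs5 counts. Rgs5 was at −1.75 without myeloid-like, endothelial and pericyte cells, the last of which were picked partly by Rgs5 itself. The potassium channel gene Kcnj8 lay at 3.66, with a count in fewer cells than the size rule asks. The medians of these lists were −0.34 and −0.43 without the top cell of each gene, and −0.52 and −0.58 without the set N2 of order 2. Of 7 tendon and ligament genes (median 0.34, percentile 95.7), Mkx was lower at −1.35. Matrix collagens (0 of 16, median 0.24, percentile 96.2) had no member past the size rule, and of 19 matrix remodelling genes (median 0.12, percentile 80.6) the gelatinase gene Mmp9 was lower at −1.78 (−1.08 without the set P1 of order 1).

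The widest list medians were those of other cell types. The endothelial list had a median of 2.63 (2.55 and 3.25 in the orders, percentile 100), although only Emcn of 14 members passed the size rule. Plvap, a protein of endothelial fenestrae, lay at 86.1 against 0.108 CPM in order 2 and Kdr, a VEGF receptor gene, at 43.4 against 0.215 CPM; both were chosen after their values were seen. The list median was 0.06 without cells holding Ptprc or Pecam1 counts, 1.01 within batches that held both groups, and 0.75 without the set P2 of order 2. The myeloid list had a median of −2.76 (percentile 0.00), from 0.16 in order 1 and −5.53 in order 2, and Fcer1g, of 18 members, was lower in both orders, at −1.84, and lay at −0.72 without cells holding Ptprc or Pecam1 counts. The B and T lymphoid list (0 of 12 passing) had −1.60 (percentile 0.00), from 0.00 and −4.26, and the mast cell and blood progenitor list −1.48 (percentile 0.01), from 0.00 and −2.52; of the latter's 11 members only Kit passed, in the other direction. Without the set N2 of order 2 the myeloid median was −1.70, the lymphoid −0.0028 and the mast cell 0.00. Of 11 erythroid genes (median 0.17, percentile 73.2), the carbonic anhydrase gene Car2 was higher at 0.98. However, Car2 lay at −0.56 without the set P2 of order 2 and at −0.11 without myeloid-like, endothelial and pericyte cells. That step did not leave out cells for erythroid markers. The 9 megakaryocyte genes (median 0.68, percentile 98.4, 0.00 without the top cell of each gene, 0.08 without the set P1 of order 1), 7 Schwann cell genes (−0.25, percentile 18.7) and 5 skeletal muscle genes (−0.36, percentile 6.86) had no member past the size rule.

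The cell cycle list had a median below 0 in order 2 alone, and most signalling lists lay near 0. The cell cycle list had a median of −1.49 (percentile 0.00), from 0.00 in order 1 and −2.55 in order 2, with 4 of 20 members lower in both orders: Top2a at −3.31, Rrm2 at −3.75, Tyms at −1.37 and Pcna at −1.35. Without the cell with the most reads in each group and order, Tyms was at −0.04, and Top2a was at 0.04 in order 1, where 1 cell held all of its 41 Tomato− counts. The median was −0.54 and Top2a at −2.61 without the set N2 of order 2, and Top2a at −0.70 without cells holding Ptprc or Pecam1 counts. Of 21 BMP and TGF-beta pathway genes (median 0.25, percentile 97.8), the decoy receptor gene Bambi was higher at 3.99 and 1.19 and the BMP target Id2 at 0.75 and 1.03. That median was 0.05 with thinned cells and −0.09 without the set P1 of order 1. Without myeloid-like, endothelial and pericyte cells the median was −0.06. Bambi was at 0.41 with all cells summed. The Hedgehog list had a median of 0.87 (percentile 99.9), from 1.15 in order 1 and 0.18 in order 2, with 0 of 11 members past the size rule. Of 20 Wnt pathway genes (median −0.22, percentile 8.21), the R-spondin receptor gene Lgr5 was lower at −2.0; 1 cell held 99.5% of its Tomato− counts of order 1, and without the top cells it was at 0.28 in order 1 and −1.07 in the mean. The 16 feedback targets of receptor tyrosine kinases, the kind of receptor that Kit is, had a median of −0.01 (percentile 43.6) with 0 past the size rule, as did 14 Notch pathway genes (0.08, percentile 64.2) and 13 genes of the insulin-like growth factor axis (−0.01, percentile 44.5).

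Of 23 immediate early and dissociation stress genes (median 0.22, percentile 97.7), Gadd45b was higher at 0.97; without the set P1 of order 1 the list lay at −0.21 and Gadd45b at −0.29, and with all cells summed they lay at −0.06 and −0.35. Of 19 inflammatory and NF-kB genes (median 0.27, percentile 97.3), the chemokine gene Ccl7 was higher at 0.98 and Ptgs2, which encodes cyclooxygenase-2, lower at −1.79; without the top cell of each group and order Ptgs2 was at −0.29, and without the set P1 of order 1 at −3.32. Ccl7 was at 0.62 without the set P2 of order 2 and at −0.05 within the sets numbered 1 of order 2. The interferon response list had a median of −0.38 (percentile 0.15), from −0.88 in order 1 and 0.03 in order 2, with 0 of 20 passing. Mitochondrially encoded genes had a median of −0.39 (percentile 0.29, 0 of 13 passing), which turned to 0.17 with all cells summed over both orders and was −0.10 without the set P1 of order 1, and the 48 ribosomal protein genes one of −0.07 (percentile 15.1) with 0 passing.

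**Figure D2:**
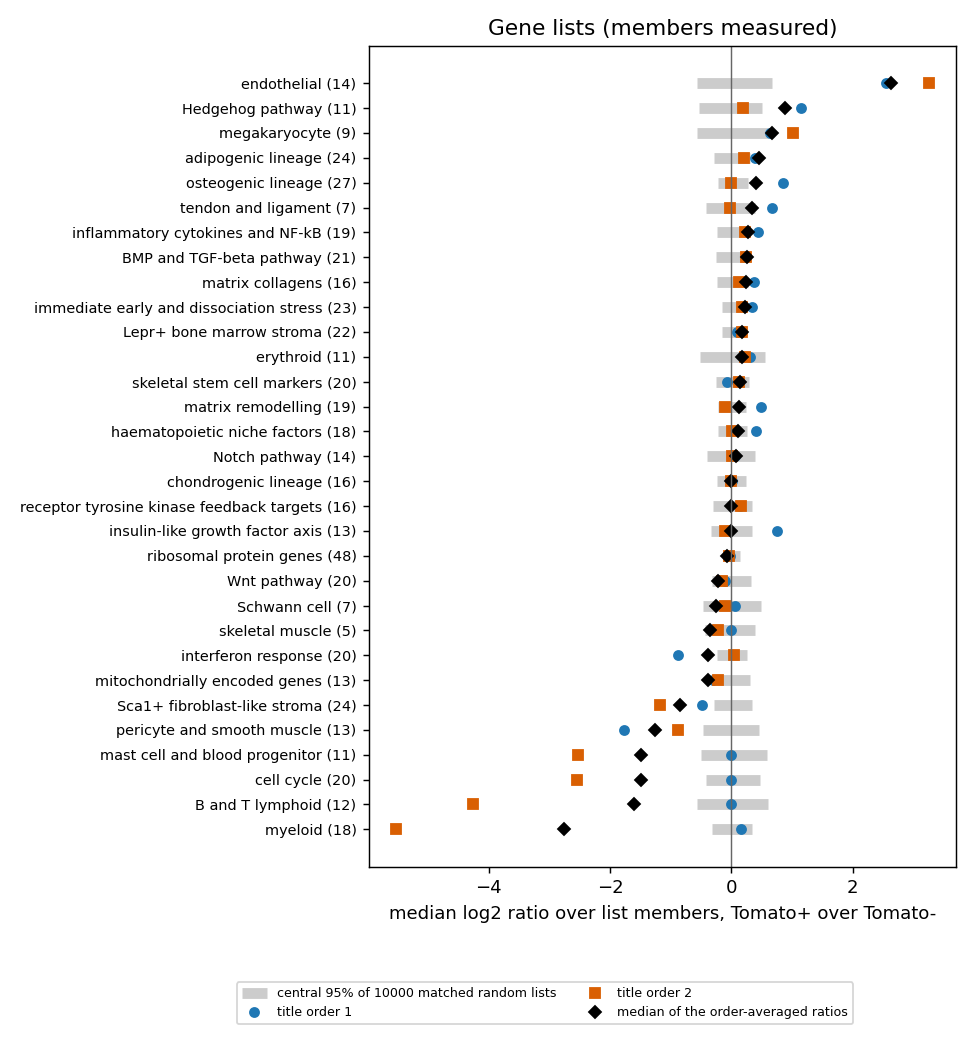
Median log2 ratio of each gene list, Tomato+ over Tomato−, with members measured in brackets; circles and squares are title orders 1 and 2, diamonds are medians of the order-averaged ratios, and grey bars are the central 95% of 10000 matched random lists. The endothelial list lies at 2.63 and the myeloid list at −2.76, the latter from 0.16 in order 1 and −5.53 in order 2.

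The third comparison asked which kinds of cell each group held. In the planned clustering, the Lepr+ stroma-like class took 100% of Tomato+ cells (98 to 100) and 95% of Tomato− cells (91 to 97.6). This was the default name for clusters led by markers of no class, so these shares alone do not identify stroma. The other 10 Tomato− cells formed a myeloid-like cluster led by S100a9, S100a8, Ngp, Lyz2 and Camp, genes of granulocytes. They made up 4.98% of Tomato− cells (2.41 to 8.96), against 0 Tomato+ cells, which allows up to 1.62%. All came from order 2, 9 of them from the set N2, where 0 of 48 Tomato+ cells allow a share of up to 6.25%, or 7.40% by the exact interval, beside the 7.09% of Tomato− cells (3.45 to 12.7), and both limits lie inside that interval. The gate excluded CD45-bearing cells, so these shares describe cells that passed it. The 7 stroma-like clusters followed the title order: clusters 0 and 1 held 88 and 87 cells of order 2, and clusters 4 to 7 held cells of order 1 only. By a rule of 3 or more detected markers per cell, myeloid markers were met in 2 Tomato+ cells (1.08%, 0.131 to 3.85), both of order 2, and 17 Tomato− cells (8.46%, 5.0 to 13.2), endothelial markers in 4 Tomato+ cells and 0 Tomato− cells (up to 1.49%), pericyte markers in 12 and 14, erythroid markers in 11 and 6, and cell cycle genes in 7 (3.78%, 1.53 to 7.64) and 17 (8.46%, 5.0 to 13.2). The class names depended on the clustering. The stroma-like shares of Tomato+ and Tomato− cells were 62.7% and 82.1% with 1000 variable genes, 62.7% and 58.7% after ComBat by title order, and 67.6% and 52.2% with 10 components, where most other cells stayed unnamed. At a resolution of 0.4 or with 10 components no myeloid-like cluster was named, and after ComBat 41 cells bore that name.

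Within the Lepr+ stroma-like class, the log2 ratios of Kit were 3.74 and 2.63 in the orders (mean 3.18). The class holds all Tomato+ cells and all but the 10 myeloid-like Tomato− cells. Its values are thus no separate check of those over all cells, and in order 1 the cells are the same. Most Tomato+ cells of the class lay in clusters 3 and 4 (54 and 47 cells) and most Tomato− cells in clusters 0 and 1 (64 cells each). The other genes higher in the class were Lrg1, a secreted leucine-rich glycoprotein, at 3.39, Vsir, an immune checkpoint receptor, at 3.49, Rfxank at 2.96, Cd300lg at 2.34 and Pak3 at 2.00. Without cells holding Ptprc or Pecam1 counts Lrg1 was at 1.32, and without myeloid-like, endothelial and pericyte cells at 1.07. Lower in the class were Fam49b at −2.99, Rrm2 at −3.20, Hist1h2ap at −2.85, Tent4a at −2.51, Hps5 at −2.13 and Rgs5 at −3.28. Among the lists, the myeloid median moved to −0.54 (percentile 1.37) and the cell cycle median to −1.06, while the endothelial (2.65), pericyte (−1.31), Sca1+ fibroblast (−0.87) and B and T lymphoid (−1.65) medians stayed near their values over all cells. The adipogenic median was 0.43, the osteogenic 0.36, the Hedgehog 0.82, the interferon −0.43 and the inflammatory 0.38 (percentile 99.5). These rested largely on order 1: the medians of orders 1 and 2 were 0.39 and 0.12, 0.86 and 0.00, 1.15 and 0.08, −0.88 and −0.06, and 0.43 and 0.14 in the same sequence. The cell cycle median in the class was 0.09 without the set N2 of order 2, and the inflammatory one −0.18 without the set P1 of order 1. Without the set N2 of order 2, Rrm2 was at −1.85, Hist1h2ap at −0.40 and the myeloid and lymphoid medians at −0.10 and −0.0034. Without the set P3 of order 1, Lrg1 was at 1.71, Vsir at 2.48 and Cd300lg at 1.53, without P1 of order 1 Rfxank was at 1.27 and Kit at 2.60, and the endothelial median was 0.75 without P2 of order 2.

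Sums of 24 cells lay about as far apart between title sets of 1 label as between the 2 labels. With 24 cells drawn from each set, the SD over genes of the log2 ratio was 1.33 between the Tomato− sets of order 2 and 1.19 between its Tomato+ sets, against 1.19 and 1.46 between Tomato+ and Tomato− sets. In order 1 it was 2.40 between the Tomato+ sets P1 and P3, against 2.30 and 2.72 between the groups. No draws from the same set were compared, so the spread between cells is not separated from differences between sets or labels. The sets P1 and P2 of order 2 hold 24 cells each, so each draw took all of them.

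**Figure D3:**
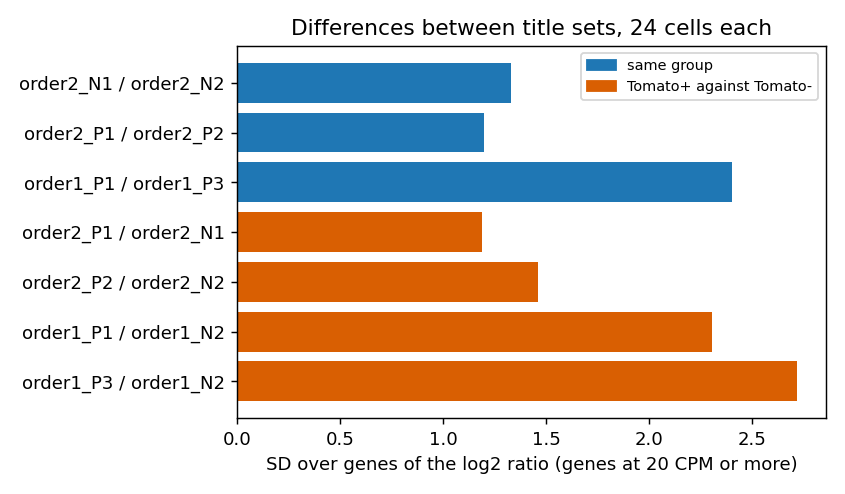
SD over genes of the log2 ratio between pairs of title sets, 24 cells drawn from each, genes at 20 CPM or more; bars for pairs of 1 group and of Tomato+ against Tomato− are coloured apart. Pairs of 1 group reach 2.40 in order 1 and 1.33 in order 2, and pairs across groups 2.72 and 1.46.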

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

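No test in this part was chosen after a result was seen. The 2 cells left out for low depth, both from the Tomato+ set P3 of order 1, still held 28 Lepr counts in sum. They stood out because this is above the 3 counts that a count of 0 allows, in cells that enter no comparison. No explanation was tested.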

How the results depend on the processing

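The alternatives chosen after the data were seen are ratios within batches that hold both groups, counts under 1% of the pool maximum set to 0, leaving out the top cell of each gene, and leaving out myeloid-like, endothelial and pericyte cells; the set P3 of order 1 was also picked for its Xist reads, and leaving out each set had been planned. List medians were treated as main results when they lay outside the central 95% of matched random lists, a rule set after the number of values to print was seen. Keeping all cells gave no value within the Lepr+ stroma-like class, since the 2 added cells have no class. No paired analysis was possible because the result comes from no test, and what the set numbers in the titles stand for is not given in the sources used here. The ratios within batches are ratios of sums under an assumed pairing of sets, and hold no test either. Each group is 1 sample, so a value that moves has no replicate error to set it against, and sums are carried by deep cells and by cells with many reads of a rare gene. The cause of a move was not tested. Cells with Ptprc or Pecam1 counts, and myeloid-like, endothelial and pericyte cells, were picked through members of the gene lists. A shift of the myeloid, endothelial and pericyte medians without such cells was therefore partly built in. A ratio or list median counts as moved when it lies further from the reported value than the SD of the 2 order values, which is wide where the orders differ, so that a large change can count as stayed. Across all alternatives, 956 ratios of named genes stayed, 236 moved and 8 reversed; within the class the numbers were 212, 64 and 0. Of list medians over all cells 584 stayed, 6 reversed and the other 23.7% moved; within the class 554 stayed, 2 reversed and 22% moved. Of shares of cells with a count, 57 stayed and 23 moved, and of class shares 27 and 33. Of the 15 main list medians over all cells, 12 to 15 had the sign of the value reported under each alternative, and of the 14 within the class 12 to 14.

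With all cells summed over both orders, the medians were 0.31 for the adipogenic, −0.057 for the stress, 0.22 for the BMP and TGF-beta and 0.17 for the mitochondrial list, with Kit at 1.68 and Gadd45b at −0.35; the stress, mitochondrial and Gadd45b values thereby changed sign. Within the class the pericyte list was at −0.69, the myeloid at −2.04, the inflammatory at 0.13, the mitochondrial at 0.14, again with a changed sign, and Kit at 2.02. Without the 10 deepest cells of each group, the adipogenic median was 0.31, the endothelial 2.07 and the BMP 0.31, and within the class the endothelial was 2.09 and the mitochondrial −0.49. Without cells holding Ptprc or Pecam1 counts, the adipogenic median was 0.18, the endothelial 0.056 and the BMP 0.16, with Emcn at −1.10 and Tspan7 at −0.64 turned in sign, and within the class the medians were 0.18, 0.056 and, for mitochondrial genes, −0.33. Without myeloid-like, endothelial and pericyte cells, the pericyte median was −0.52, the endothelial 0.033 and the BMP −0.057, with Emcn at −1.37, Tspan7 at −0.30 and Car2 at −0.11; these 3 genes and the BMP median thereby turned. Within the class the pericyte and endothelial medians were −0.52 and 0.033. Within batches that hold both groups, the adipogenic median was 0.22, the Sca1+ fibroblast −1.44 and the endothelial 1.01, and within the class the adipogenic was 0.17 and the endothelial 1.03.

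Without the top cell of each gene, medians over all cells were 0.29 for adipogenic, −0.34 for Sca1+ fibroblast, −0.43 for pericyte, 1.2 for endothelial, 0.00 for megakaryocyte, 0.34 for stress, 0.29 for BMP and −0.29 for mitochondrial genes. Within the class they were −0.19 for Sca1+ fibroblast, −0.47 for pericyte, 1.29 for endothelial, 0.00 for megakaryocyte and −0.32 for mitochondrial genes. At a pseudocount of 0.1 CPM the Sca1+ fibroblast median was −1.97, the endothelial 4.40, the megakaryocyte 1.74 and the BMP 0.27, and within the class they were −2.01, 4.43 and 1.74, with Kit at 4.03. At a pseudocount of 5 CPM the endothelial median was 1.44, the megakaryocyte 0.20 and the BMP 0.27, with Kit at 1.98, and within the class the Sca1+ fibroblast median was −0.35, the endothelial 1.44, the megakaryocyte 0.20 and the mitochondrial −0.36, with Kit at 2.09. Over members at 20 CPM or more the adipogenic median was 0.32. The BMP median was 0.10 with per-cell means, 0.23 with TMM factors, 0.21 with DESeq2 size factors and 0.051 with thinned cells. The mitochondrial median within the class was −0.37, −0.44, −0.46 and −0.30 in the same order, and −0.29 over all thinned cells. The SD between title sets of 1 group in order 1 was 2.30 with per-cell means. Over genes at 100 CPM or more it was 1.90 within a group and 2.01 between groups in order 1, and 0.891 and 0.993 in order 2, against mean values of 2.40, 2.51, 1.26 and 1.32 at 20 CPM.

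The share of Lepr+ stroma-like cells in Tomato+ and Tomato− cells was 82.3% and 84.6% with thinned cells, 70.8% and 88.1% at resolution 1.2, and 62.7% and 82.1% with 1000 variable genes. It was 62.7% and 58.7% after ComBat by title order, 67.6% and 52.2% with 10 components, and 85.6% and 89.6% among cells with 2000 or more genes. At resolution 0.4 it was 100% in Tomato− cells. Myeloid-like cells were 11.9% and 9.45% after ComBat, and 0% of Tomato− cells with 10 components and at resolution 0.4. With 5 counts or more required, Pdgfra was met in 76.8% of Tomato+ and 78.1% of Tomato− cells, Ptprc in 0% and 5.97%, Kit in 9.19% and 3.98%, and Pecam1 in 7.03% and 7.46%, an order of the groups opposite to that with 1 count. With counts under 1% of the pool maximum set to 0, Pdgfra was met in 66.5% and 69.2%, Lepr in 89.2% and 84.1%, Kit in 11.4% and 6.47%, Ptprc in 10.4% of Tomato− cells, and Pecam1 in 10.8% of Tomato+ and 9.45% of Tomato− cells. After thinning, Pdgfra was met in 84.5% and 89.4%, Ptprc in 9.04% of Tomato− cells, and Pecam1 and Kit in 9.94% and 13.8% of Tomato+ cells. Genes of low level are thus limited by depth in these shares.

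Leaving out 1 title set at a time, the adipogenic median ran from 0.20 (without N2 of order 1) to 0.51, the pericyte from −1.71 to −0.58 (N2 of order 2), the endothelial from 0.75 (P2 of order 2) to 3.52, and the Hedgehog from 0.18 (N2 of order 1) to 1.11. The set P1 of order 1 gave the lowest megakaryocyte (0.076 to 1.02), stress (−0.21 to 0.30) and BMP (−0.094 to 0.28) medians, the lowest value of Gadd45b (−0.29 to 1.13) and the mitochondrial median nearest 0 (−0.50 to −0.10). Car2 ran from −0.56 (P2 of order 2) to 1.92. Within the class the same sets gave the extremes: adipogenic 0.12 to 0.46, pericyte −1.70 to −0.58, endothelial 0.75 to 3.54, megakaryocyte 0.12 to 1.11 and mitochondrial −0.53 to −0.12. The cell cycle median there ran from −1.48 to 0.086 (N2 of order 2) and the inflammatory from −0.18 (P1 of order 1) to 0.62. Without N2 of order 1 only order 2 remains, and the interferon and osteogenic medians were 0.035 and 0.00. Without N2 of order 2 the B and T lymphoid median was −0.0028 and the mast cell median 0.00 over all cells and 0.14 within the class. Lepr+ stroma-like shares ran from 67.6% to 100% in Tomato+ and from 54.6% to 96% in Tomato− cells, and myeloid-like shares from 0% to 9.73% and from 0% to 37.7%, and the lowest stroma-like and highest myeloid-like shares came without the set N1 of order 2. Ptprc shares ran from 0% to 2.20% and from 6.87% to 22.7%.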

Other observations

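Tests of the top cell of Kit, of Kit reads in cells of any other type, of S100a8 and Lepr reads in myeloid-like cells and of cells with different sex-linked reads were chosen only after the result was seen, as were the genes named in the next paragraph.

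Beyond granulocyte genes, Tomato− cells of order 2 carried transcripts of other blood lineages. The B cell precursor genes Dntt, Igll1 and Cd79a lay at 70.2, 37.3 and 29.1 CPM in Tomato− and at 0.193, 0.0643 and 0.0643 CPM in Tomato+ cells, and Cpa3, a mast cell protease gene, at 76 against 0.257 CPM. Markers of lymphoid cells were met in 2 Tomato− cells and 0 Tomato+ cells (up to 1.62%), and those of mast or progenitor cells likewise in 2 and 0. Without the cell with the most reads in each group and order, the order-averaged ratios of Dntt, Igll1, Cd79a and Cpa3 went from −2.95, −2.59, −2.41 and −2.97 to −1.57, −2.07, −1.64 and −1.17, and the median of the lymphoid list was −0.0028 without the set N2 of order 2. Among Tomato+ cells of order 2, the fatty acid carriers Fabp4 and Cd36 lay at 369 and 28.2 CPM, against 3.73 and 0.0108 CPM in Tomato− cells, although their ratios in order 1 were 0.35 and 0.12. Single cells carried much of this: the order-averaged ratios of 3.32 and 2.49 were 1.37 and 0.67 without the cell with the most reads in each group and order, and that of Fabp4 was 0.96 within batches that hold both groups.

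The title sets differed in their sex-linked reads. In order 1, Xist reads alone were found in 19 of 60 Tomato− cells and Y-linked reads alone in 9, in the set P3 in 20 and 1 of 38 cells, and in the set P1 in 0 and 59 of 94 cells. In order 2, Y-linked reads alone were found in 52 of 71, 53 of 70, 19 of 24 and 21 of 24 cells of the sets N1, N2, P1 and P2, and Xist reads alone in 1, 9, 0 and 1.

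The first pattern weighed is the higher Kit level of Tomato+ cells, at a log2 ratio of 3.02. After counts under 1% of the highest count of the same library pool were set to 0 the ratio was 3.16. That step removes only low counts and could hardly lower a ratio of sums, so it does not decide on reads from other wells. The share of cells with a Kit count fell from 20% to 11.4% in Tomato+ and from 11.4% to 6.47% in Tomato− cells. Without the cell with the most Kit reads in each group and order the ratio was 2.88, which argues against single cells. Of the Tomato+ Kit counts 4.29% lay in the 6 cells with endothelial, myeloid, lymphoid, megakaryocyte or mast cell markers, and 25.8%, between the bounds set, in 38 cells when erythroid, pericyte and Schwann cell markers were counted too; without all such cells the ratio was 4.21, which argues against them as the whole cause. In 20 simulations without change the smaller order ratio of the top-ranked gene reached 2.55, above the 2.29 of Kit. That value is the highest among many genes, whereas Kit was a gene fixed before the data were examined. The comparison therefore cannot decide on chance between cells for Kit alone, which stays open. Continued Kit transcription in descendants and a difference between animals, which the labels do not name, were not tested.

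The second pattern is the 10 myeloid-like cells, all Tomato− and of order 2. In 8 of them S100a8 reached 32.6% or more of the highest count of its pool, assumed to be the title set and plate row. These 8 were picked for a share of 10% or more, so that share is no separate test of reads from other wells. For 17 genes found almost only in 1 cell of order 2, the mean count of pool mates had a median of 0.0174% of the top count. These genes were picked because every other cell held under 5% of the top count. Wider sharing was thus left out by the choice, and the value sets no upper limit on it. Lepr lay at 22.8 to 204 CPM in the 8 cells, 0.479% to 4.29% of the other cells of their sets with a median of 0.755%. This low Lepr level argues against a stromal cell in the same well, and 6 of the 8 carried Xist reads. The other 2 held 21320 and 19881 counts, S100a8 at 0.159% and 0.168% of the pool maximum and a median Lepr level of 94.2% of other cells, so that reads from a neighbouring well are a candidate source of their class; a CPM bound set at first was dropped because such shallow cells pass it with a few stray reads, at 5206 CPM. Over all 10 cells the median Lepr level was 2.29%, a value that mixes both kinds. Too few Tomato+ cells of order 2 stay an open explanation for finding none: the exact upper limit of 7.40% for 0 of 48 cells reaches the 7.09% of Tomato− cells, although the 6.25% that 3 counts would make lies below it, both limits reach the 5.67% that the 8 cells with high S100a8 make up, and 2 of those 48 cells held 3 or more myeloid markers.

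The third pattern is that clusters of order 1 followed the library code, with an adjusted mutual information of 0.560. Setting counts under 1% of the pool maximum to 0, which removed 0.386% of counts, brought it to 0.0337, a share of 0.0602 of the value before, while that of cluster and title order went from 0.502 to 0.477. In order 1, genes found almost only in 1 cell of the order had counts in 55.9% of its pool mates and 5.87% of cells of other pools. The mean count of pool mates had a median over these genes of 0.0560% of the top count. In order 2, with the assumed pools, the shares were 32.6% and 4.89%. Tomato− cells with Xist reads alone were also set beside Tomato+ cells with Y-linked reads of the same pool. Of the former, 19 of 19 (a share of 1) lay in the cluster of most of the latter. Clusters already followed the library code, so this cannot decide whether different animals stood in different pools. Given the fall of the adjusted mutual information to 0.0337, reads shared within a pool may shape these clusters.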
